A study of Mus musculus with 8 samples.

How the data were processed

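RNA was measured in 3T3-L1 cells, an established mouse preadipocyte line that turns into fat-storing adipocytes under a hormone cocktail. Per the labels, mature adipocytes at day 10 were harvested 72 hours after infection with an adenovirus. The 4 control cultures (group LACZ) received a virus carrying beta-galactosidase, and the 4 treated cultures (group PU1) received a virus carrying the full-length mouse cDNA of PU.1, a transcription factor of blood cells encoded by Spi1. Per the series' design text, replicates are separate differentiations and infections, with 1 array each. Groups and replicate numbers were taken from the sample titles.

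Total RNA with a spike-in mix was labelled with Cy3 and hybridised to 1-colour Agilent mouse arrays, per the labels' protocols. Per the file headers, the intensity of each spot was extracted with Agilent Feature Extraction 10.7.3.1, and the array design was annotated on mm9. The deposited processed intensity is background-subtracted and detrended but not scaled between arrays. The deposited flags mark spots that are well above background, saturated or outliers, per the file headers. The deposited table of log2 values holds 55681 probes and had a median of 5.34 in every column. Its columns had equal distributions and a Spearman correlation of 0.9999 to 1.0 with the scanner intensities, so its scale was taken to be quantile-normalized log2 intensity, unscaled by gene and with no direction. The submitters' processing notes name limma, and the version is not given in the sources used here. All columns of that table belong to the 8 samples.

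Each array carried 59305 non-control spots for 55681 probes. The files pair probes with accessions and not with gene symbols. Unversioned accessions were matched to a table of mouse RefSeq genes on assembly GRCm38.p6, which named 26582 probes for 20145 genes. The other 29099 probes, standing for 17063 distinct features, are unnamed here. No coordinates are given, since the array design and this table use different builds.

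The main setting was log2 of the processed intensity minus each array's 75th percentile over non-control probes. Spots of a probe were averaged and spots marked as outliers were left out. This left 124 single probe values missing. Probes were kept when well above background on all 4 arrays of at least 1 group, with at least 2 values per group, which left 33515 probes for 24642 features, of which 14499 were named genes. A gene was represented by its kept probe with the highest mean. Differences (PU1 minus LACZ) were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group only), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Counts below are of named genes. Where no probe of a gene was well above background on any array of a group, the change is given as a bound, "at least N-fold". The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. The same bound is given for rises of single genes whose probe was well above background on some or none of the LACZ arrays. A bound compares means and leaves out their sampling error. That lowest value lay between -6.11 and -5.27 on the normalized log2 scale. No spot was saturated (0 on each array).

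Before the data were examined, 20 gene lists were fixed, together with the tests and the rule for named genes. That rule takes Spi1, Pparg and Cebpa, and the 8 largest rises and 8 largest falls among genes that passed, did not overlap between groups and were well above background on all 8 arrays. It adds the 5 largest bounds per direction, and up to 3 passing members per list with the largest change, plus the largest in the other direction. Features without a symbol and clone or predicted names were passed over. One gene that the rule names is not reported here. Lists were tested with camera, a test within limma of whether a list moved relative to the other named genes, with a preset inter-gene correlation of 0.01 and adjustment over the 20 lists. Camera with an estimated correlation, fry and a two-sided exact permutation test of the list mean per array were run beside it. With 4 arrays against 4, the smallest p the exact test allows is 0.0286.

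The array column on the slide equals the replicate number, so the numbers could mark a shared position. Deviations from the group means correlated at 0.35, 0.11, 0.22 and 0.22 between same-numbered arrays, and all 8 arrays correlated best with the array of their own number in the other group. The numbers were therefore treated as pairing the arrays, from the labels and this check, and the fit with the number as a block is the paired analysis. All arrays lay on 1 slide and in 1 scan, so slide could not be a block. The 4 LACZ arrays filled one row of the slide and the 4 PU1 arrays the other, so row and group cannot be told apart.

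The alternatives were normexp background correction (offset 50), quantile normalization, median centring, spike-in scaling over the 10 spike-in control probes, no filter, a filter requiring all 8 arrays, the deposited value table, the mean over a gene's probes, each probe on its own, the replicate block, array weights, eBayes with trend and robust, each array left out in turn, and a threshold of 0.01. Normexp was run on median spot signals, since the mean signal is not a column of these files. The spike-in probes are named for an early gene of adenovirus and the vectors were adenoviral, and whether the vectors lack that gene is not stated in the sources used here. Scaling by the 8 spike-in probes well above background on every array was added after the data were seen, as were the list means within pairs and the bounds for genes above background on some LACZ arrays. The fit was tested on simulated arrays of 33519 probes for this comparison. It called 9 of 50 probes changed by 0.5 on the log2 scale, 43 of 50 changed by 1, 48 of 50 changed by 2 and 50 of 50 changed by 4, and 9 of 33319 unchanged probes. Camera called 10 of 10 shifted and 0 of 30 unchanged simulated lists. Probes varied independently in these simulations, while the estimated correlations within the real lists reached 0.641. How often camera calls unchanged lists of correlated genes was therefore not tested by simulation. Splits of the real arrays that balance PU1 and LACZ, described below, bear on it in part. The precision is limited by the number of arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.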

Results

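The data comprised 8 single-colour arrays of differentiated 3T3-L1 adipocytes, 4 from cultures infected with the control beta-galactosidase virus (LACZ) and 4 from cultures infected with the PU.1 virus (PU1). The comparison addresses how forced expression of a haematopoietic transcription factor changes RNA levels in mature fat cells. Between 57.8% and 72.8% of spots were well above background on the LACZ arrays and between 62.5% and 65.1% on the PU1 arrays. The 72.8% came from LACZ replicate 2, on which 29.7% of the external control (ERCC) spots were also well above background, against 10.3% to 16.1% on the other arrays. Arrays of one group correlated at 0.994 to 0.995 across features and arrays of different groups at 0.936 to 0.951, where features are not independent replicates. The first principal component held 85.9% of the variance. The groups occupied different rows of the slide, so row and group cannot be told apart.

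Spi1, the gene encoding PU.1, was not well above background on any LACZ array and was well above background on all 4 PU1 arrays. Its signal relative to the array's 75th percentile was -7.55 on average in LACZ and 2.00 in PU1 on the log2 scale, a rise of at least 220-fold (limma adjusted p = 2.69e-09). The array holds 1 probe for Spi1. Whether its sequence lies within the transferred cDNA was not determined, so transcripts of the vector and of the cells' own gene were not told apart.

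PU1 and LACZ adipocytes differed in 8353 of 14499 named genes at an adjusted p under 0.05 in limma. Of these, 3424 were higher in PU1 and 4929 were lower. At a change of at least 2-fold, the order turned, with 1396 genes higher and 948 lower. These counts were 926 and 590 with normexp correction, 1771 and 548 with spike-in scaling, and 913 and 831 when signal was required on all 8 arrays. The 4 PU1 values lay all above or all below the 4 LACZ values in 54.5% of named genes, where chance gives 2.86%. The split between rises and falls followed the scaling. Falls made up 59.0% of the passing genes under the 75th percentile and 32.3% when arrays were scaled by the spike-in controls, with 4035 genes then higher and 1925 lower. The median change over named genes moved from -0.11 to 0.13 on the log2 scale between these scalings. The camera tests below compare each list with the other named genes, while counts and median differences of a list follow the scaling.

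Among genes well above background on all 8 arrays, the largest rises included Oas1f, an oligoadenylate synthetase of the antiviral response (log2 difference 9.96, SE 0.11), Bst1, a cell-surface enzyme of myeloid and stromal cells (9.65, SE 0.17), Rtp4 (9.23, SE 0.15) and Usp18, a protease that removes Isg15 from proteins (8.76, SE 0.15). Csprs, Apol9b, Ifi44 and Pla1a completed the 8 largest, with differences of 9.02, 7.69, 7.64 and 7.48. The differences at the 3 probes of Csprs ranged from 2.33 to 9.02, and those at the 2 of Bst1 from 7.23 to 9.65. The largest falls were of Fa2h, a fatty acid hydroxylase, which fell by 4.18 (SE 0.25), Il1rl1, a cytokine receptor, which fell by 4.00 (SE 0.46; -2.14 at its other kept probe), and Syt13, a synaptotagmin, which fell by 3.91 (SE 0.28). Trp53i11, Wfdc21, Hp, Fosl1 and Podnl1 fell by 3.53, 3.49, 3.45, 3.28 and 3.22. All of these had limma adjusted p-values of 0.000173 or lower (n = 4 per group).

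Several genes passed from below background to a clear signal. Pirb, a receptor of myeloid cells, rose at least 1948-fold, Ifit1 at least 1204-fold, Rsad2, the antiviral protein viperin, at least 1126-fold, Cd300c2 at least 851-fold and Arhgap9 at least 829-fold. In the other direction, Uts2, which encodes urotensin, was lower in PU1 by at least 3.42 on the log2 scale, followed by Tprg (at least 6.2-fold), Bdkrb1, a bradykinin receptor (at least 6.07-fold), Pgbd5 (at least 5.83-fold) and Tnfsf11, the ligand RANKL (at least 4.84-fold). All 10 had limma adjusted p-values of 7.27e-05 or lower.

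**Figure D1:**
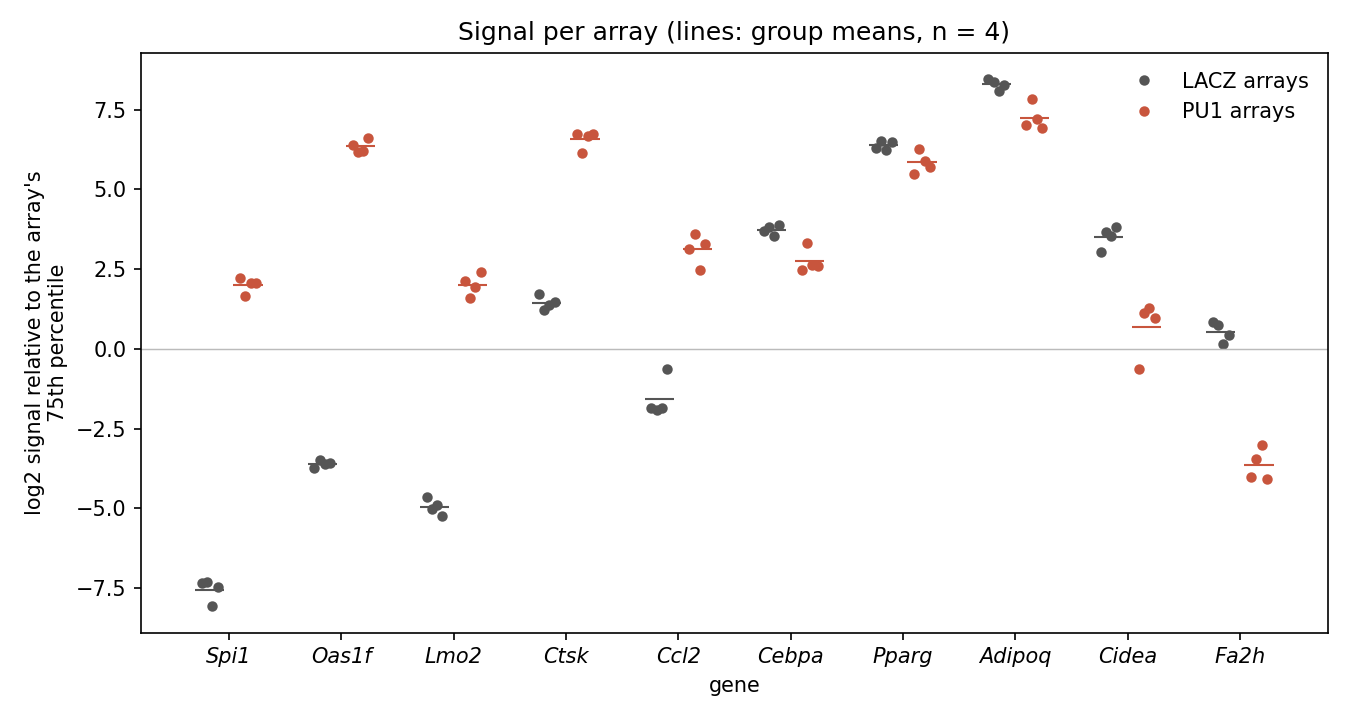
Log2 signal relative to each array's 75th percentile for 10 genes (Adipoq was chosen after its values were seen), with 1 point per array and a line at each group mean (4 LACZ and 4 PU1 arrays). The LACZ values of Spi1 are not well above background, and the PU1 points lie above the LACZ points for Spi1, Oas1f, Lmo2, Ctsk and Ccl2 and below them for Cebpa, Adipoq, Cidea and Fa2h, while for Pparg the highest PU1 value (6.28) lies above the lowest LACZ value (6.25).

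Genes of the interferon response rose together. All 34 measured members were higher in PU1 and 0 were lower, with a median log2 difference of 5.91, also when genes below background in LACZ were set at their bound. The bound for the rise was 7741-fold for Oas2, with 3 of 4 LACZ arrays well above background, and 6475-fold for Oas1a, with 1 of 4. Without the bound, the 95% intervals were 6729 to 9510 and 5050 to 8301, so sampling error reaches below both bounds. The list stood 6.03 above the other named genes (camera adjusted p = 3.33e-29), a call that held with an estimated correlation (adjusted p = 0.034). Genes of antigen presentation behaved alike, with 21 of 21 members higher, a median difference of 2.72 and 2.39 with bounds (camera adjusted p = 1.19e-14; adjusted p = 0.0214 with an estimated correlation). The class II genes H2-Aa and H2-Ab1 were higher by at least 30.5-fold and by 67.2-fold (95% interval 36.5 to 124), and Psmb8, a subunit of the immunoproteasome, by 47.8-fold (41.7 to 54.9).

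Markers of macrophages and myeloid cells were higher for 25 of 32 measured genes and lower for 1, with a median log2 difference of 3.50, or 3.08 with bounds (camera adjusted p = 4.4e-13; adjusted p = 0.0214 with an estimated correlation). Tyrobp, a signalling adaptor of myeloid receptors, rose at least 900-fold, with 1 of 4 LACZ arrays well above background, and Cd53, a leukocyte tetraspanin, rose at least 115-fold. Itgam, which encodes an integrin of macrophages, was the gene with a fall, of 0.96 (SE 0.15) at its brightest probe. Its 3 probes disagreed, with a highest probe difference of 3.54, and the mean over probes rose by 0.86. Genes of the list on the array that were not well above background on all arrays of either group, and so were not tested, were C1qa, C1qc, Cd86, Clec4e, Fcgr1, Laptm5, Lilrb4a and Msr1.

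Genes of the phagocyte oxidase and of haematopoietic signalling were higher for 23 of 27 and lower for 2, with a median difference of 2.82, or 2.13 with bounds (camera adjusted p = 1.17e-11; adjusted p = 0.0214 with an estimated correlation). Cybb, a subunit of the oxidase, Lcp2 and Arhgap30 were not well above background on all arrays of either group and were not tested. The single genes named here are signalling genes, not oxidase subunits. Inpp5d, an inositol phosphatase of blood cells, rose at least 161-fold. Blnk, an adaptor of B cell and myeloid signalling, rose at least 106-fold, with 1 of 4 LACZ arrays well above background. Fermt3, an integrin activator of blood cells, fell by 0.68 (SE 0.12), a call lost with spike-in scaling (a difference of -0.44; adjusted p = 0.0692, over alternatives from 0.000751).

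Of 25 haematopoietic transcription factors measured, Spi1 included, 13 were higher and 5 lower (camera adjusted p = 0.00513; adjusted p = 0.417 with an estimated correlation). The list's mean log2 difference was 1.68 and its median 0.29, and no test without Spi1, the gene carried by the PU1 virus, was run. Gata1, Gfi1, Ikzf1, Myb, Nfe2, Pax5, Spib and Tal1 were not well above background on all arrays of either group and were not tested. Lmo2, a factor of early blood cells, rose by 6.97 (SE 0.18) and Cebpe, a granulocyte factor, at least 13.6-fold. The erythroid factor Klf1 fell by 1.61 (SE 0.14). Among genes above background on all 8 arrays, the list's call was lost (relative difference 0.41 against 1.59, camera adjusted p = 0.395). Lymphoid, erythroid and mast cell genes gave no list call (camera adjusted p = 0.399), with 4 of 15 measured genes higher, 2 lower, a mean difference of 0.54 and a median of -0.04. Cpa3, a mast cell protease, rose at least 6.17-fold, and Cd79b, a component of the B cell receptor, rose at least 9.76-fold, with 1 of 4 LACZ arrays well above background. Lck, a T cell kinase, rose by 1.19 (SE 0.14), and Prtn3, a neutrophil protease, fell by 0.69 (SE 0.24, limma adjusted p = 0.0372), with an exact permutation p of 0.0571. The Prtn3 call was lost without LACZ replicates 2, 3 and 4 in turn (differences of -0.59, -0.70 and -0.65), with spike-in scaling (-0.45) and with no filter. Without PU1 replicate 1, the array farthest from the rest of its group, the difference was -0.45, and the adjusted p ranged from 0.0023 to 0.133 over the alternatives.

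Inflammatory cytokines and chemokines were higher for 15 of 25 measured genes and lower for 2 (camera adjusted p = 0.0001; adjusted p = 0.16 with an estimated correlation). Il1b, a central inflammatory cytokine, rose at least 23-fold. The chemokines Ccl6 and Ccl2 rose 26.2-fold (95% interval 14.6 to 47.0) and 25.8-fold (15.4 to 43.2). Hp, which encodes haptoglobin, fell 10.9-fold. Lysosomal genes were higher for 21 of 30 and lower for 1 (camera adjusted p = 6.88e-06; adjusted p = 0.569 with an estimated correlation). Ctsk, the collagen-degrading protease cathepsin K, rose 35-fold (27.2 to 45.1), the proton pump subunit Tcirg1 5.0-fold (3.6 to 6.94) and progranulin (Grn) 4.41-fold (3.68 to 5.27). The cholesterol exporter of the lysosome, Npc1, fell 2.45-fold (1.93 to 3.11).

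Genes for storing and releasing fat were lower in PU1 for 19 of 28 and higher for 0, with a median log2 difference of -0.76 (camera adjusted p = 0.000976; adjusted p = 0.611 with an estimated correlation). Cidea, a lipid droplet protein, fell 7.1-fold, Pck1, which makes glycerol precursors, 5.23-fold, and the phosphatidate phosphatase Lpin1 2.83-fold. With spike-in scaling, 14 of the 28 were lower and 1 was higher. Lipogenic genes were lower for 10 of 18 and higher for 2 (camera adjusted p = 0.0161; adjusted p = 0.611 with an estimated correlation). The mitochondrial citrate carrier Slc25a1 fell 3.61-fold, malic enzyme Me1 2.9-fold and the desaturase Scd1 2.21-fold. With spike-in scaling, 6 of the 18 were lower. Acly, the ATP citrate lyase, rose by 0.53 (SE 0.17, limma adjusted p = 0.027; exact permutation p = 0.0571), a call lost with the replicate block (adjusted p = 0.0666) and with no filter (0.0619). It was also lost without LACZ replicate 2 or 3 (differences of 0.50 and 0.40) or PU1 replicate 2 or 3 (0.44 and 0.48), and its adjusted p ranged from 0.00275 to 0.0696 over the alternatives.

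**Figure D2:**
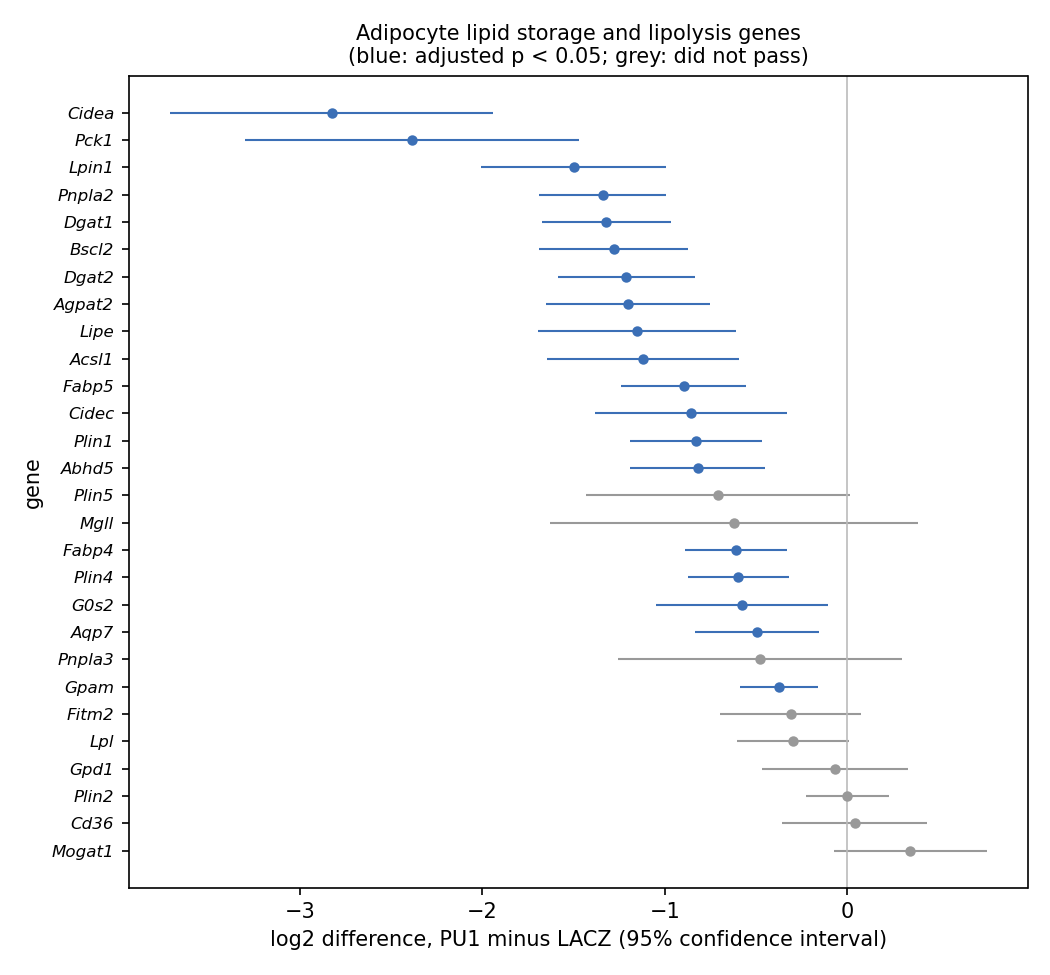
Log2 difference (PU1 minus LACZ, n = 4 arrays per group) of the 28 measured genes for lipid storage and lipolysis, with 95% confidence intervals. Blue marks the 19 genes that passed an adjusted p under 0.05, all of them lower in PU1 (14 with spike-in scaling), and grey the 9 that did not pass.

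Adipokine and insulin response genes were lower for 11 of 21 and higher for 2. The list's call was the weakest of those fixed lists that passed (camera adjusted p = 0.0305; adjusted p = 0.611 with an estimated correlation), and it was lost without LACZ replicate 4 (relative difference -0.74), without PU1 replicate 1 (-0.69), among genes above background on all 8 arrays (-0.65), under quantile normalization (-0.70) and in the deposited value table (-0.69). Resistin (Retn) fell 4.34-fold, the beta adrenergic receptor Adrb3 4.16-fold and the retinol carrier Rbp4 3.98-fold. The adrenergic receptor Adra2a rose 2.11-fold, a change that normexp correction reduced to 0.29 on the log2 scale (adjusted p = 0.0932, over alternatives from 1.14e-05).

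Adipogenic transcription factors gave no list call (camera adjusted p = 0.323), with 12 of 21 lower and 4 higher, or 5 lower and 4 higher with spike-in scaling. Pparg, the central factor of fat cell differentiation, was lower in PU1 within each same-numbered pair. It fell by 0.54 (SE 0.16, limma adjusted p = 0.0203), with an exact permutation p of 0.0571 from a test that ignores the pairing. This call was lost under quantile normalization (a difference of -0.38), in the deposited value table (-0.38), under spike-in scaling (-0.30), and without LACZ replicate 2 (-0.49) or PU1 replicate 4 (-0.49), and its adjusted p ranged from 0.00265 to 0.239 over the alternatives. Cebpa, its partner in differentiation, fell by 0.99 (SE 0.18, limma adjusted p = 0.0019). Rxra, the dimer partner of Pparg, fell 2.56-fold at its brightest probe, while its other probe differed by 0.26, and the coactivator Ppargc1a fell 2.36-fold. Klf4 rose 2.42-fold.

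Genes of fatty acid oxidation and brown fat were lower for 16 of 22 and higher for 1 (camera adjusted p = 0.0144; adjusted p = 0.611 with an estimated correlation). Cox7a1 and Cox8b, respiratory chain subunits typical of brown fat and muscle, fell 6.57-fold and 3.47-fold, and the deiodinase Dio2 3.53-fold. Cpt1a, which carries fatty acids towards the mitochondrial matrix, rose 2.87-fold. Oxidative phosphorylation genes were lower for 27 of 30 and higher for 0, with a median difference of -0.53 (camera adjusted p = 8.68e-06; adjusted p = 0.611 with an estimated correlation). Idh3a, Cyc1 and Cox7b fell 2.4-fold, 1.9-fold and 1.74-fold. With spike-in scaling, 8 of the 30 were lower. Cholesterol synthesis genes were lower for 15 of 24 and higher for 0 (camera adjusted p = 0.00148; adjusted p = 0.611 with an estimated correlation), and the falls of Tm7sf2, Hsd17b7 and Lss, enzymes of the pathway, were 2.43-fold, 2.42-fold and 2.39-fold. With spike-in scaling, 9 of the 24 were lower.

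Preadipocyte and fibroblast genes were higher for 11 of 23 and lower for 4 (camera adjusted p = 0.0161; adjusted p = 0.611 with an estimated correlation). The surface antigen Ly6a rose 18.6-fold (95% interval 15.3 to 22.7) and Wnt6 3.49-fold (2.12 to 5.74). Cd34 rose at least 6.54-fold at a probe that was well above background on 0 of 4 LACZ arrays. Pdgfra, a receptor of fibroblasts and fat progenitors, fell 2.12-fold (1.32 to 3.41). Extracellular matrix genes gave no list call (camera adjusted p = 0.399), with 13 of 31 lower and 4 higher, or 6 lower and 5 higher with spike-in scaling. The gelatinase Mmp9 rose at least 23.1-fold and thrombospondin (Thbs1) 14.3-fold, and the proteoglycan lumican (Lum) fell 4.65-fold.

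The other 3 lists did not pass. Cell cycle genes were lower for 15 of 34 and higher for 6 (camera adjusted p = 0.231), and with spike-in scaling for 12 and 8. Ccnd1, a cyclin of early cell cycle entry, and the replication helicase subunit Mcm5 rose 6.01-fold and 3.19-fold, and Ccne2 fell 4.94-fold. Apoptosis and p53 target genes were lower for 10 of 26 and higher for 7 (camera adjusted p = 0.899), with a mean difference of 0.03, a median of -0.16 and a test direction that was down. With spike-in scaling, 2 were lower and 8 higher. The death-promoting genes Bcl2l11 and Apaf1 rose 4.27-fold and 2.47-fold, and the death receptor Tnfrsf10b fell 2.22-fold. Unfolded protein and stress response genes were lower for 13 of 26 and higher for 5 (camera adjusted p = 0.208), and with spike-in scaling for 5 and 5. Haem oxygenase (Hmox1) fell 3.57-fold and Atf3 rose 2.63-fold. The heat shock protein gene Hspb1 fell 2.22-fold (limma adjusted p = 0.0289; exact permutation p = 0.114), a call lost under spike-in scaling, with no filter, without LACZ replicates 1, 3 and 4 in turn (log2 differences of -1.08, -0.90 and -1.07) and without PU1 replicates 2 and 3 in turn (-1.0 and -1.15). Its adjusted p ranged from 0.000576 to 0.0734 over the alternatives.

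**Figure D3:**
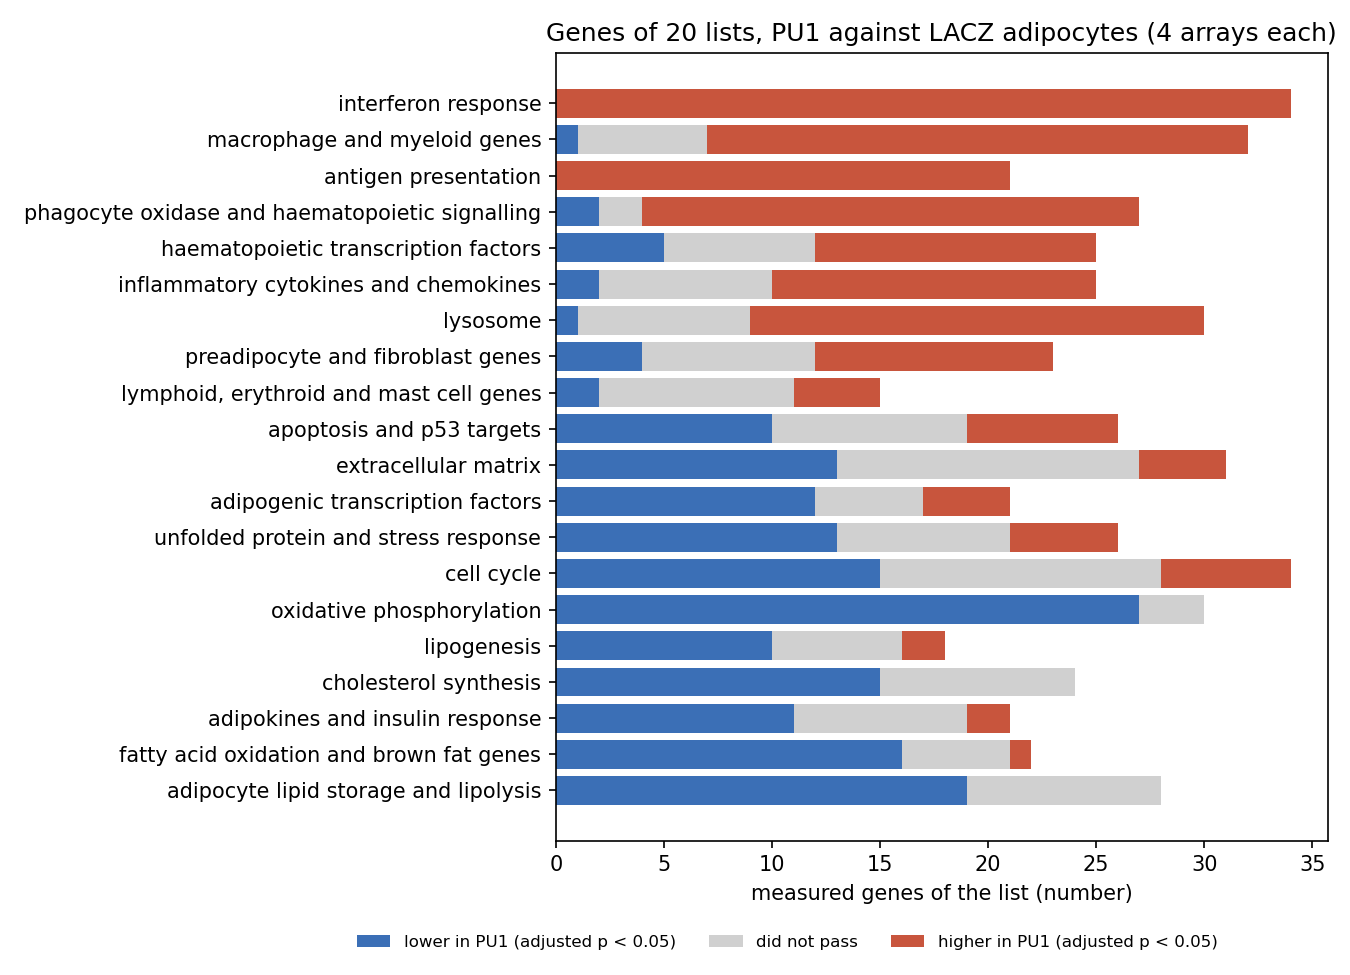
Number of measured genes in each of the 20 lists that were lower in PU1 (blue), did not pass (grey) or were higher in PU1 (red) at a limma adjusted p under 0.05, with lists ordered by their mean change relative to the other named genes. The interferon response (34 of 34) and antigen presentation (21 of 21) bars are wholly red, and oxidative phosphorylation (27 of 30) is nearly all blue, where spike-in scaling gives 8 of 30 lower.

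In all, 14 of the 20 lists passed camera with the preset correlation, 4 with an estimated correlation (interferon response, antigen presentation, macrophage and myeloid genes, phagocyte oxidase and haematopoietic signalling) and 18 in fry, which tests whether a list's genes move one way and compares them with no others. The exact permutation test of the list mean, which ignores the pairing by number, gave its smallest p (0.0286, or 0.0336 adjusted over the lists) for most lists. The exceptions were cell cycle (0.114), apoptosis and p53 targets (0.371) and extracellular matrix (0.886). Within the same-numbered pairs, the list mean was lower in PU1 in 4 of 4 pairs for cell cycle, higher in 4 of 4 for apoptosis and p53 targets, and higher in 2 of 4 for extracellular matrix. The exact p of a paired sign-flip test was 0.75 for extracellular matrix and 0.125 for every other list. The smallest p that 4 pairs allow is 0.125, so the paired test could call no list. Adjusted over the list alone, the counts differed from those over all genes for some lists and equalled them for the rest. They were 11 lower for lipogenesis, 2 higher for fatty acid oxidation, 3 lower for macrophage and myeloid genes, 14 higher and 6 lower for haematopoietic transcription factors, 16 higher and 3 lower for inflammatory genes, 2 lower for lysosome and 16 lower for cell cycle.

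The mean spike-in control signal relative to the 75th percentile was 1.00 ± 0.11 on the log2 scale (SD, n = 4) in LACZ and 0.76 ± 0.19 in PU1, a difference of -0.24 (two-sided exact permutation p = 0.114). Without PU1 replicate 3 the difference was -0.34, at the smallest exact p allowed (0.0286). The slope of the spike-in signal against its brightness rank was 1.88 ± 0.06 in LACZ and 1.86 ± 0.04 in PU1 (two-sided exact permutation p = 0.714, n = 4 each).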

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

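Each value below belongs to 1 array whose distance from the other 3 arrays of its group exceeded Dixon's 95% critical ratio. Of 252 groups of 4 values tested, 19 held such an array, where chance gives about 12.6 (1 in 20). No explanation was tested for these values.

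LACZ replicate 1 was dimmer than the other LACZ arrays, with a median spot signal of 21.4 against 44.9 to 49.0 and a mean log2 spike-in signal of 9.31 against 10.24 to 10.42. The SD of the negative control spots was 24.2 signal units on LACZ replicate 4 and 0.49 to 2.88 on the others. The spike-in signal relative to the 75th percentile was 1.05 on PU1 replicate 3 and 0.65 to 0.68 on the other PU1 arrays.

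The mean of the preadipocyte and fibroblast genes was lowest on both arrays numbered 1, at 1.04 on LACZ replicate 1 (others 1.44 to 1.52) and 1.74 on PU1 replicate 1 (others 2.07 to 2.13).

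Single genes also stood apart, in log2 signal relative to the 75th percentile. On LACZ replicate 4, Hp was at 7.58 (others 5.87 to 6.0), Pgbd5 at -3.82 (-3.16 to -3.05), Itgam at 5.28 (5.60 to 5.66) and Ccl2 at -0.63 (-1.92 to -1.84). On LACZ replicate 3, Uts2 was at -2.02 (-2.56 to -2.49) and Klf1 at -1.76 (-1.62 to -1.61). On LACZ replicate 1, Rsad2 was at -6.80 (-7.74 to -7.66) and Mmp9 at -7.23 (-7.59 to -7.58), values that were not well above background. On PU1 replicate 1, Cidea was at -0.62 (0.98 to 1.27), Fermt3 at -3.37 (-3.58 to -3.55) and Prtn3 at -3.48 (-2.58 to -2.46). Without PU1 replicate 1 the difference of Cidea was -2.39. Ctsk was at 6.13 on PU1 replicate 2 (6.68 to 6.74), and Mcm5 at 1.12 on PU1 replicate 4 (0.19 to 0.24).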

How the results depend on the processing

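Scaling by the 8 bright spike-in probes was chosen after the data were seen. Over the alternatives other than leaving out an array, 350 of 378 values of counts, lists and the PU.1 level kept their direction and their side of the threshold (counts within 1.5 times), 14 lost the call, 5 gained it and 9 counts moved further. Of 1366 values of single genes, 1337 kept both, 23 lost the call, 5 gained it and 1 changed sign: Itgam rose by 0.86 in the mean over probes. The replicate block called 9236 genes (3729 higher, 5507 lower), 8218 of them shared with the unblocked fit in the same direction, and ended no call of a list.

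Normexp called 1516 genes at 2-fold (926 higher, 590 lower). Spike-in scaling called 1925 lower genes, 548 at 2-fold, and the cell cycle list passed (-0.38, adjusted p = 0.0431). The bright spike-in scaling called 5551 genes, 1873 lower and 559 lower at 2-fold. A total of 5348 genes were called in the same direction under the 75th percentile and spike-in scaling, and 0 in opposite directions. Requiring signal on all 8 arrays left 913 genes higher at 2-fold, since genes off in one group are not tested there, and ended the calls of haematopoietic transcription factors (0.41) and adipokines (-0.65). The adipokine call was also lost under quantile normalization (-0.70) and in the deposited value table (-0.69). Apart from the count of 913, the cause of these changes was not tested.

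With an estimated correlation, calls were lost, with relative differences as before, for lipid storage (-0.93), lipogenesis (-0.67), adipokines (-0.77), fatty acid oxidation (-0.81), oxidative phosphorylation (-0.64), preadipocyte (0.56), lysosome (0.61), cholesterol synthesis (-0.73), haematopoietic transcription factors (1.59) and inflammatory genes (1.37). The estimated correlations of these lists ranged from 0.0882 to 0.641, above the preset 0.01, which widens their error. Fry, which compares no list with other genes, also called adipogenic transcription factors (-0.24), lymphoid, erythroid and mast cell genes (0.54), cell cycle (-0.29) and unfolded protein response (-0.26).

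Leaving out each array in turn gave 7367 to 7987 genes, an adipokine list difference from -0.90 to -0.69 (call lost without LACZ replicate 4, -0.74, or PU1 replicate 1, -0.69) and a spike-in difference from -0.34 (without PU1 replicate 3) to -0.20. Slide as a block was not run, since there was 1 slide, nor were list tests with each probe on its own. Signal over background limits genes off in one group to bounds.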

Other observations

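The glycolysis and osteoclast lists were chosen after the values were seen, as were the single genes named only in this part. So were the tests for a lower share of adipocytes and for macrophages. None of these tests can bear an explanation out. Those for adipocyte share and macrophages use genes picked with their values known, so they cannot exclude one either. Genes of glycolysis and the hypoxia response were lower in PU1 for 24 of 27 and higher for 0 (relative log2 difference -1.01, camera adjusted p over 5 added lists = 4.89e-05; adjusted p = 0.394 with an estimated correlation). The carbonic anhydrase Car9 fell by 2.82 (SE 0.62), Ero1a, an oxidase of the endoplasmic reticulum, by 2.52 (SE 0.16), and the growth factor Vegfa by 1.13 (SE 0.10). With spike-in scaling, 17 were lower and 1 was higher. Mitochondrial ribosomal protein genes were lower for 29 of 42 (camera adjusted p = 0.00023; adjusted p = 0.394 with an estimated correlation) and cytosolic ribosomal protein genes for 16 of 56 (camera adjusted p = 0.00416; adjusted p = 0.674 with an estimated correlation), with 0 higher in both. With spike-in scaling these numbers were 4 and 0. Constitutive proteasome genes did not pass (camera adjusted p = 0.573), with 6 of 31 higher and 6 lower, or 7 higher and 1 lower with spike-in scaling.

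Genes of osteoclasts, the bone-resorbing cells of the myeloid lineage, were listed after Ctsk, Mmp9 and Tcirg1 were seen to rise, and with these included 8 of 15 were higher and 0 lower (median difference 0.40, relative difference 1.11, camera adjusted p = 0.000242; adjusted p = 0.0429 with an estimated correlation). Without these 3 genes, 5 of 12 were higher, with a median of 0.28 and a relative difference of 0.26 (camera p = 0.0108 with the preset correlation, not adjusted). Ocstamp rose by 1.46 (SE 0.10) and the acid phosphatase Acp5 by 1.04 (SE 0.26), and Nfatc1 rose by 1.20 (SE 0.09) at its brightest probe, while its other probe differed by -0.07. Car2 (-1.17), Oscar (0.05) and Itgb3 (0.35) did not pass. Ifnb1, which encodes interferon beta, was not well above background on any LACZ array and rose at least 38.1-fold (limma adjusted p = 2.56e-07). The interferon alpha genes Ifna1 and Ifna2 differed by 0.17 and -0.14 (limma adjusted p = 0.317 and 0.341).

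Whether chance could give such counts was tested over the 35 splits of the 8 arrays into 4 and 4. The real split gave the most changed genes, 8353 against at most 5 in any other, and likewise at 2-fold, with 2344 against at most 5 (1 of 35 splits as large for each). The other splits mix PU1 and LACZ arrays, so a group difference counts there as spread and lowers the count. Their low counts therefore do not show what chance alone would give. For the number of lists passed, chance cannot be excluded by this test, since 6 of 35 splits gave 14 or more and the highest other split gave 15. The highest other counts among the 8 splits that part all 4 same-numbered pairs were 0 genes, 0 at 2-fold and 14 lists. The 16 splits that share 3 arrays per group with the real one, and so keep part of its difference, gave up to 15 lists. The 18 that share 2 gave at most 10. In these the group difference cancels in the means, so camera with the preset correlation called lists there without it. Those that also part all 4 same-numbered pairs gave 0, 1 and 6 lists. The group difference stays in their spread, so the rate of such calls in arrays without one was not measured. All 14 called lists had their largest shift in the real split, as had 17 of all 20 lists. The other splits shrink or cancel a group difference, so this lends the called lists no support.

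That more genes fell than rose may follow from the array scaling. The share of falls among passing genes was 59.0% under the 75th percentile and 32.3% under spike-in scaling, the lowest of the scalings tried. The spike-in difference between the groups did not pass its exact permutation test (p = 0.114), and the spike-in probes share their adenoviral origin with the vectors. The spike-in mix was labelled together with total RNA, so neither scaling measures amounts per cell. Which scaling is nearer the amounts in the labelled RNA stays open.

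The fall of lipid storage genes could reflect scaling, a lower share of adipocytes or lower expression per adipocyte. Against scaling as the whole cause, 14 of 28 members still fell under spike-in scaling, the fewest of any scaling. Adipoq, Cfd, Fabp4, Plin1, Cidec and Retn did not fall by one common amount, with changes from -0.25 (Cfd) to -2.12 (Retn). The SD of their log2 changes was 0.633, against at most 0.561 in the other splits of the arrays, a narrow margin. These genes were picked with their values known, and Retn lay apart from the rest. The split with 0.561 shares 3 arrays per group with the real one. The spread of these genes alone therefore cannot exclude a lower adipocyte share as the whole cause. Adipoq relative to Cfd, a pair picked from these genes, was -0.67 ± 0.12 (SD, n = 4) in LACZ and -1.47 ± 0.32 in PU1 (two-sided exact permutation p = 0.0286). Genes of preadipocytes and fibroblasts moved both ways, with 11 of 23 higher and 4 lower. A lower share of adipocytes, as the whole cause or a part of it, and lower expression per cell as a hypothesis, stay open.

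The rise of interferon and myeloid genes could come from PU.1, from macrophages in the cultures or from a higher virus dose. For 8 transcripts abundant in macrophages, the median change was 0.196 (interquartile range 1.02). It was 4.24 for the 26 called genes of the macrophage and myeloid list. With values under the background floor set to it, these medians were 0.02 (0.27) and 3.32. The 8 belong to the same list and were picked with their values known, while the 26 were selected for passing. This contrast therefore cannot exclude macrophages. Of these 8, C1qb (0.02) and Ptprc (0.35) did not pass and Lyz2 rose at least 6.36-fold, while 3 were well above background on no PU1 array, and other members of the list rose, among them Ctss (at least 66.6-fold), Mpeg1 (6.39) and Aif1 (4.94). Macrophages as a cause stay open, although the cells were an established preadipocyte line. A higher virus dose cannot be told apart from an effect of PU.1, since 0 probes, spike-in controls aside, are named for a viral transcript of both vectors. An effect of PU.1, the difference that the design names, stays open as untested.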
